A study of Mus musculus with 10 samples.

How the data were processed

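Labelled RNA from sorted mouse bone marrow cells was hybridised in 1 colour (Cy3) to Agilent arrays of the 4x44K format, with probe coordinates on mouse build mm9 per the file headers. The 10 arrays fall into 4 groups by gate and genotype: 3 LSK WT, 3 LSK Msi2Gt, 2 KIT WT and 2 KIT Msi2Gt. The labels state that marrow of 4 females aged 6 to 7 weeks was combined per genotype, that 25 ng of RNA was used, and, in the series description, that the replicates are technical.

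The scanner files of the 10 arrays hold, per the file headers, the intensity of each spot as Agilent Feature Extraction 10.7.3.1 gave it with protocol GE1_107_Sep09. The processed signal is background-subtracted and detrended within its array, and no normalization between arrays had been applied to it. The files also hold the mean intensity and the local background of each spot and flags for spots well above background, saturated or non-uniform. The authors' deposited table holds log2 values from 5.66 to 19.22, with a line per non-control spot. Its normalization is not stated by the submitters; the 10 columns have the same distribution, with medians of 7.45 to 7.46. They match quantile-normalised values of a normexp background correction (offset 50) to a median absolute difference of 0.0027 to 0.0032 log2 units per array.

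From the scanner files the log2 of the processed signal was taken, and each array's 75th percentile over its 43020 non-control spots was subtracted. That percentile was an intensity of 1034.5 to 2126.2. Spots with a non-uniformity or population outlier flag, 100 to 245 per array, were set to missing, and saturated spots were to be kept, of which there were 0. Spots of a probe were averaged to 39429 probes with 31829 gene names. A probe was tested if it was well above background on every array of at least 1 group, and the brightest probe stood for its gene, which left 22555 genes. Where 0 arrays of the lower group were well above background, the fold change is a lower bound, written "at least": each array of that group was taken at the lowest signal called well above background on it, or at its own signal if higher. Signal over background is the measure of depth, and the report gives the share of spots above background for each array. Intervals from counts do not apply to arrays.

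Groups were compared with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean per group over all 10 arrays, 6 residual and 1.63 prior degrees of freedom, and moderated statistics (eBayes, two-sided). The 5 comparisons were Msi2Gt against WT in LSK and in KIT cells, LSK against KIT in WT and in Msi2Gt, and the interaction, that is the change in LSK cells minus that in KIT cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison, and calls with a change of at least 2-fold were also counted. All fold changes are log2, Msi2Gt minus WT or LSK minus KIT, with the standard error of the moderated fit (SE). Tables were read with jsonlite 2.0.0 and data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

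Gene groups were tested with limma's camera with an inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison. Beside it, each member's call was counted over all genes and adjusted over the list alone. The lists, written from general knowledge and not chosen on these samples, were Musashi, Numb and Notch; haematopoietic stem cell; leukaemia self-renewal; lymphoid priming; granulocyte-monocyte progenitor; megakaryocyte and platelet; erythroid; haemoglobin and late erythroid; mast cell, basophil and eosinophil; G1/S; G2/M; cell-cycle inhibitors and quiescence; immediate early and cell stress; interferon response; Ras and MAPK signalling; TGF-beta signalling; and, for other cells a gate could hold, B cell, T and NK cell, macrophage, mature granulocyte, MHC class II and dendritic cell, and stroma and endothelium. The groups, comparisons, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined.

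The rule for named genes took every Msi2 probe; for each comparison, the 5 largest increases and the 5 largest decreases among called genes with a gene symbol whose probe was above background on every array of the higher group; in the genotype comparisons, at most 4 called members of each list by size of change, or the member with the lowest p where none was called; in the gate comparisons, at most 2 called members per list; and Ly6a and Kit. Some list members that the rule takes are left out of the text. Genes or gene families named outside the rule are said to be chosen after their values were seen.

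The alternatives tried were normexp background correction (offset 50), quantile normalization, scaling to the median of probes above background on all arrays, the authors' table, no filter on dim probes, a filter over all 10 arrays, the mean over a gene's probes, a fit on the groups of the comparison alone, an intensity trend in the prior, array weights, the replicate number as a block, slide as a fixed or random block, and leaving out each array in turn. For the lists these were camera with an estimated correlation, fry, quantile normalization, the replicate block and leaving out each array; camera with normexp, median scaling and the authors' table was added after seeing the data. The arrays lay on 5 slides: slide 1 held LSK WT replicate 1, slide 2 replicate 1 of LSK Msi2Gt and of both KIT groups with LSK WT replicate 2, slide 3 LSK WT replicate 3 and KIT WT replicate 2, slide 4 LSK Msi2Gt replicate 2, and slide 5 LSK Msi2Gt replicate 3 and KIT Msi2Gt replicate 2. Changes were therefore also computed within slide 2, with no test. The arrays of a slide are also in the fit, so the sign of a called gene within a slide was close to fixed in advance. The replicate numbers of the titles were checked for pairing, by correlating deviations from the group mean across genes between arrays of different groups. The median r was 0.105 for the 13 pairs of arrays with the same number and 0.266 for the 8 pairs on the same slide. It was -0.164 for the 19 pairs that shared neither. Some pairs shared both, and pairs with an array in common are not independent, so the check is weak. The numbers were not used as pairs.

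The procedure was tested on simulated data with 22424 genes, 200 of them changed. Of genes given a change of 1 log2 unit, 59.7% were called in LSK cells, 59.7% in KIT cells and 37.3% by the interaction term, and of those given 2 units 90.9%, 83.3% and 77.3%. False calls were 3.91%, 8.26% and 4.82% of all calls. A shifted list of 25 genes was called by camera (adjusted p = 2.06e-35) and 0 of 20 unchanged lists were. The simulated noise was independent between genes and arrays, with no slide effect, and the lists were random genes. The simulation therefore cannot show the rate of false calls for correlated genes, real lists or arrays that share a slide. Its 200 changed genes are also a smaller share than was called in any comparison of the real data. The Benjamini-Hochberg threshold depends on that share, so the percentages recovered do not carry over to the real comparisons. Control spots were left out, and every sample of the series was used.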

Results

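The series measured gene expression in blood-forming cells of mice with a gene trap (Gt) in both copies of Msi2, which encodes the RNA-binding protein Musashi 2, and in wild-type (WT) C57/Bl6 mice. The bone marrow of 4 females aged 6 to 7 weeks was combined for each genotype, lineage-positive cells were removed, and 2 populations were sorted. LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive) hold the stem cells and the earliest progenitors. KIT cells (lineage-negative, Sca-1-negative, c-Kit-positive) hold the more committed myeloid and erythroid progenitors. Each array was hybridised with labelled RNA from 1 sample: 3 arrays for LSK WT, 3 for LSK Msi2Gt, 2 for KIT WT and 2 for KIT Msi2Gt. The replicates are technical per the series description, so p-values measure only the spread between arrays of a pool, and genotype cannot be separated from the pool, its sort and its handling. The labels do not call the WT mice littermates and do not give the insertion site. The number of arrays limits the precision.

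On the LSK WT arrays 67.5%, 76.5% and 68.5% of the non-control spots were well above background, and on the LSK Msi2Gt arrays 71.3%, 71.6% and 76.0%. The KIT WT arrays had 68.2% and 64.2% such spots, and the KIT Msi2Gt arrays 64.1% and 66.4%. No array had a saturated spot (0 on each). Across genes, which are not independent replicates, Pearson's r between arrays of a group was 0.985 to 0.994 in LSK WT, 0.992 to 0.994 in LSK Msi2Gt, 0.991 in KIT WT and 0.994 in KIT Msi2Gt. The first principal component held 77.2% of the variance and separated LSK arrays (-101.2 to -66.8) from KIT arrays (119.4 to 132.6). The second held 8.71%: LSK Msi2Gt arrays lay at -46.7 to -31.3 and LSK WT arrays at 33.7 to 52.9. KIT Msi2Gt arrays lay at -21.7 and -15.9 on it, and KIT WT arrays at 1.87 and 15.0. LSK WT replicate 2 stood apart from its group on the third component (5.02% of the variance), at -61.0 against 11.01 and 25.9.

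**Figure D1:**
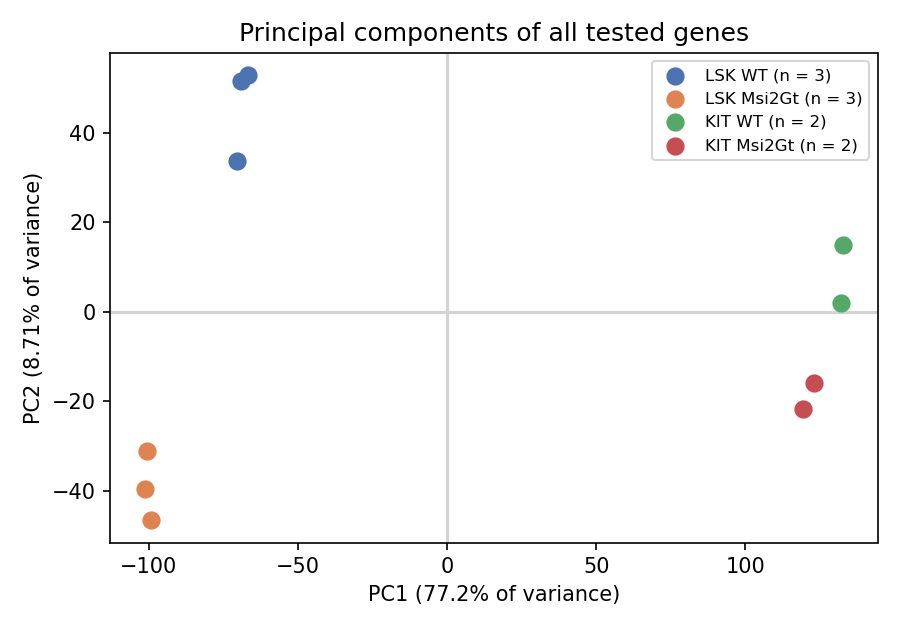
Each point is an array at its scores on the first (x axis) and second (y axis) principal components of log2 signal, coloured by group. LSK arrays lie below 0 and KIT arrays above 0 on the first component, and within each gate every Msi2Gt array lies below every WT array on the second.

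The gene the trap targets was measured by 3 probes. The brightest, A_55_P1992045 (transcript NM_054043, mm9 chromosome 11, 88152912 to 88152971), gives the Msi2 values unless another is named. Its log2 signal relative to the array's 75th percentile was 3.93, 3.98 and 3.99 on the LSK WT arrays and 2.47, 2.59 and 2.54 on the LSK Msi2Gt arrays. In KIT cells it was 2.35 and 2.56 in WT against -2.52 and -2.57 in Msi2Gt. Msi2 RNA thus fell by 1.43 log2 units in LSK cells (SE 0.07, limma adjusted p = 1.21e-05), to 37.1% of the WT level, and by 5.00 in KIT cells (SE 0.09, adjusted p = 6.19e-07), to 3.12%. The fall was smaller in LSK cells by 3.57 log2 units (SE 0.11, adjusted p of the interaction term = 2.78e-05). With slide as a block the changes were -1.43 and -4.95, and within slide 2, which alone holds both genotypes of a gate, -1.51 and -4.87. In WT mice Msi2 was 1.51 log2 units higher in LSK than in KIT cells (SE 0.08, adjusted p = 1.49e-06).

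The other 2 Msi2 probes, A_55_P1992040 and A_55_P2004624, are assigned to a predicted transcript (XM_001471946) 394.3 kb away, at 88547287 to 88547346 and 88547261 to 88547320. They were dim, with WT means of -5.25 and -5.82 in LSK cells, and moved the opposite way. In LSK cells they rose by 1.91 (SE 0.10) and 1.82 (SE 0.29), with adjusted p over all probes of 1.24e-05 and 0.00318. In KIT cells the first rose by 0.93 (SE 0.12, adjusted p = 0.00419). The second was above background on 0 of 2 KIT WT arrays and 1 of 2 KIT Msi2Gt arrays.

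**Figure D2:**
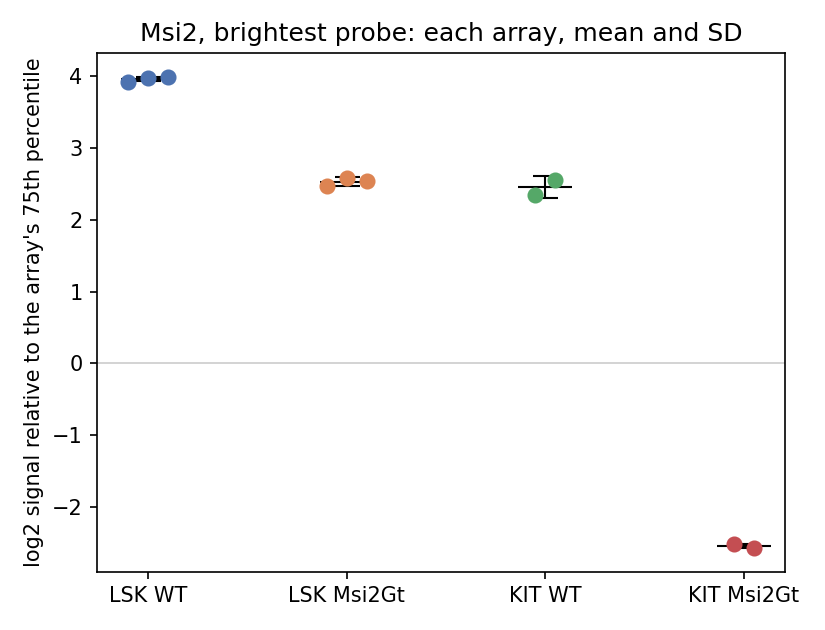
Log2 signal of the brightest Msi2 probe relative to the array's 75th percentile (y axis) in the 4 groups (x axis), with a point per array and lines for the mean and SD. The LSK Msi2Gt arrays stay between 2.47 and 2.59, while the KIT Msi2Gt arrays fall to -2.52 and -2.57.

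The comparison of Msi2Gt with WT LSK cells asks how expression differed in the gate that holds the stem cells and the earliest progenitors. The gate was measured in bulk, so a changed mix of its cells cannot be told apart from changes within cells. Immediate early genes and genes of granulocyte-monocyte and lymphoid progenitors fell, while genes of the haematopoietic stem cell list rose. Fos and Jun, which pair in the AP-1 transcription factor, fell by 8.48 log2 units (SE 0.16) and 5.22 (SE 0.11). Ctsg, the neutrophil granule protease cathepsin G, fell by 2.72 (SE 0.07), and Dntt, which adds nucleotides to rearranging antigen receptor genes, fell by 2.41 (SE 0.10). Sult1a1, a sulfotransferase on the stem cell list, rose by 2.06 (SE 0.14). Of 22555 genes tested, 2820 rose and 2795 fell past the threshold, 5615 in all; which direction had more changed with the setting, as with quantile normalization (2639 and 2828). A change of at least 2-fold was fitted for 1443 of them, 987 up and 456 down, and 1389 with genes below background in the lower group held at their bound.

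Among the 5 largest increases, Ccnb1ip1, a ubiquitin ligase known from meiosis and located on chromosome 14, was at least 12.5-fold higher (adjusted p = 4.93e-06). The sialyltransferase gene St6galnac2 rose by 5.45 (SE 0.08, adjusted p = 1.43e-07) and Cfd, encoding complement factor D, by 4.68 (SE 0.18, adjusted p = 4.49e-06). St6galnac2 lies on chromosome 11, between 10 and 30 Mb from Msi2. Ighg, an immunoglobulin gamma heavy chain, was at least 7.15-fold higher (adjusted p = 0.000258) and the BMP receptor gene Bmpr1a at least 6.37-fold (adjusted p = 0.000191). The 5 largest decreases, led by Fos (adjusted p = 4.04e-07) and Jun (8.08e-07), held 2 genes of cartilage and joint matrix. Col10a1, a collagen chain, was at least 26.2-fold lower (adjusted p = 0.00301), and Prg4, which encodes lubricin, at least 6.66-fold lower (adjusted p = 9.95e-06). Slfn8, of the Schlafen family and within 20 Mb of Msi2, fell by 5.07 (SE 0.41, adjusted p = 0.000103). Its other probe gave -0.22 (adjusted p = 0.118).

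The immediate early and cell stress list, transcripts that rise within minutes of stimulation, moved most. Of its 25 tested members 20 fell and 0 rose (21 and 0 adjusted over the list alone), with a mean change of -1.93 and a camera adjusted p of 8.8e-19. Fosb, another AP-1 subunit, fell by 4.74 (SE 0.18), and Dusp1, a phosphatase that switches off MAP kinases, by 2.90 (SE 0.12). With slide as a block the list's mean was -1.93, and within slide 2 it was -1.94.

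Lists of lineage-restricted progenitors were lower. In the granulocyte-monocyte progenitor list 20 of 24 fell and 0 rose (21 and 0 adjusted over the list alone), with a mean of -1.08 and an adjusted p of 1.01e-16. Beside Ctsg, F13a1, the coagulation factor XIII A chain, fell by 3.09 (SE 0.11), Ms4a3 by 1.92 (SE 0.08) and haptoglobin (Hp) by 1.67 (SE 0.08). The lymphoid priming list had 14 of 27 members lower and 2 higher (16 and 2 over the list alone), with a mean of -0.57 and an adjusted p of 8.01e-06. The recombinase genes Rag1 and Rag2 fell by 1.77 (SE 0.22) and 2.18 (SE 0.20), and the interleukin 7 receptor gene Il7r by 1.59 (SE 0.19). The means of these 2 lists were -1.07 and -0.61 with slide as a block, and -1.14 and -0.64 within slide 2.

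Erythroid, megakaryocyte and mast cell lists shifted less. The erythroid list had 13 of 30 members lower and 2 higher (14 and 2 over the list alone), with a mean of -0.30 and an adjusted p of 0.000624. Ctse, an aspartic protease, fell by 2.50 (SE 0.07) and the erythroid transcription factor gene Gata1 by 0.78 (SE 0.08). In the megakaryocyte and platelet list 11 of 24 fell and 4 rose, the same counts over the list alone, with a mean of -0.35 and an adjusted p of 0.0118. Itga2b and Itgb3, the chains of the platelet fibrinogen receptor, fell by 1.96 (SE 0.12) and 1.76 (SE 0.06). For mast cells, basophils and eosinophils 7 of 18 fell and 2 rose (9 and 3 over the list alone), with a mean of -0.42 and an adjusted p of 0.00435. Hdc, which makes histamine, fell by 1.70 (SE 0.08) and the mast cell carboxypeptidase gene Cpa3 by 1.45 (SE 0.06).

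The haematopoietic stem cell list had 22 of 36 members higher and 1 lower (23 and 2 over the list alone), with a mean of 0.53 and an adjusted p of 8.27e-08. Besides Sult1a1, Hoxb5 rose by 1.45 (SE 0.12), the drug efflux pump gene Abcb1a by 1.23 (SE 0.13) and the transcription elongation factor gene Mllt3 by 1.23 (SE 0.10). Hoxb5 lies within 20 Mb of Msi2. The list's mean was 0.54 with slide as a block and 0.50 within slide 2. Of the genes used for the sort, Ly6a (Sca-1) changed by -0.21 (SE 0.08, adjusted p = 0.0835) and Kit rose by 0.29 (SE 0.08, adjusted p = 0.0412).

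Cell-cycle lists were lower. For G1/S and DNA replication 20 of 35 fell and 1 rose (23 and 1 over the list alone), with a mean of -0.31 and an adjusted p of 2.52e-07. Mcm2 and Mcm3, subunits of the replicative helicase, fell by 0.87 (SE 0.08) and 0.65 (SE 0.06), whereas the cyclin gene Ccnd1 rose by 1.29 (SE 0.07). For G2/M and mitosis 16 of 30 fell and 0 rose, the same over the list alone, with a mean of -0.30 and an adjusted p of 2.35e-07. Cks2, a partner of cyclin-dependent kinases, fell by 0.65 (SE 0.07) and Top2a, topoisomerase II alpha, by 0.42 (SE 0.08). The interferon response list also fell, with 16 of 30 members lower and 1 higher (18 and 1 over the list alone), a mean of -0.42 and an adjusted p of 3.21e-06. The antiviral genes Mx1 and Ifit3 fell by 1.25 (SE 0.09) and 1.39 (SE 0.14), and Usp18, which removes the ISG15 modifier, by 1.42 (SE 0.08). These 3 lists, blocked by slide, had means of -0.29, -0.28 and -0.45, and within slide 2 -0.29, -0.29 and -0.49.

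Markers of other cells that a gate could hold moved in both directions. In the B cell list 3 of 11 rose and 0 fell (4 and 0 over the list alone), with a mean of 0.55 (0.31 with normexp, 0.21 in the authors' values) and an adjusted p of 0.0403. That call was lost with adjusted p = 0.194 with an estimated correlation. The macrophage list had 7 of 16 higher and 2 lower, over the list alone too, with an adjusted p of 0.211; Mrc1, the mannose receptor, rose by 2.27 (SE 0.19) and the adhesion molecule gene Vcam1 by 1.71 (SE 0.07). Stroma and endothelium had 5 of 18 higher and 7 lower (7 and 8 over the list alone; adjusted p = 0.492). Its type I collagen genes Col1a1 and Col1a2 fell by 4.69 (SE 0.16) and 3.11 (SE 0.09), while Flt4, the VEGF receptor of lymphatic endothelium, rose by 2.73 (SE 0.12). Mature granulocyte genes had 1 of 13 higher and 5 lower (adjusted p = 0.0605), T and NK cell genes 3 of 16 higher and 2 lower (0.920), haemoglobin and late erythroid genes 3 of 14 higher and 2 lower (0.866), and MHC class II and dendritic cell genes 4 of 18 higher and 4 lower (0.866).

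Signalling lists had members on both sides and none passed camera. Ras and MAPK signalling had 9 of 37 higher and 4 lower (adjusted p = 0.672), with Rasgrp1, a Ras activator, up by 2.17 (SE 0.13). TGF-beta signalling had 6 of 22 higher and 5 lower (0.869), with the inhibitor of differentiation gene Id3 up by 1.91 (SE 0.13). The leukaemia self-renewal list had 4 of 21 higher and 5 lower (0.869), cell-cycle inhibitors and quiescence 5 of 22 higher and 6 lower (0.920), and Musashi, Numb and Notch 3 of 16 higher and 4 lower (0.920). In the last of these Dll1, a Notch ligand, rose by 1.95 (SE 0.20) and Dtx4 fell by 1.51 (SE 0.08). Nr4a1, an orphan nuclear receptor on the quiescence list, fell by 2.31 (SE 0.09).

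Past the threshold in LSK cells were 11 of the 22 lists, and the calls of 10 hold with an estimated correlation. All 11 kept the sign of their mean with slide as a block, where the largest difference was 0.18, and within slide 2, where it was 0.13. Mean and test differed in sign for T and NK cells (0.18, lower), Musashi, Numb and Notch (0.03, lower), haemoglobin (mean 0.05, median -0.09, lower) and cell-cycle inhibitors (mean -0.16, median -0.01, higher). For TGF-beta signalling the mean was 0.05 and the median -0.0036. The mean changed sign with quantile normalization for MHC class II, with the authors' table for T and NK cells, with both for haemoglobin, and with both and normexp for the Musashi list. The B cell call was lost without LSK WT replicate 3 (adjusted p = 0.0528) or LSK Msi2Gt replicate 1 (0.0541), and mature granulocyte genes passed without LSK WT replicate 1 (0.0252). With quantile normalization the B cell list did not pass (0.0804) and the mature granulocyte list did (0.0259, and 0.0296 in the authors' values). A slide block, which leaves 2 residual degrees of freedom, left 715 genes called. All called genes kept their direction then and within slide 2 (100%). The slide 2 arrays, LSK WT replicate 2 among them, are also in the fit, so the kept direction is no separate support. The slide block ended calls of Col10a1, Gata1, Mcm2, Mcm3, Cks2, Top2a, Hoxb5, Abcb1a, Ifit3, Rag1, Rag2, Il7r, Dll1 and Kit, of genes named here. With normexp Rag1 and Kit lost theirs, and in the authors' values Top2a.

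**Figure D3:**
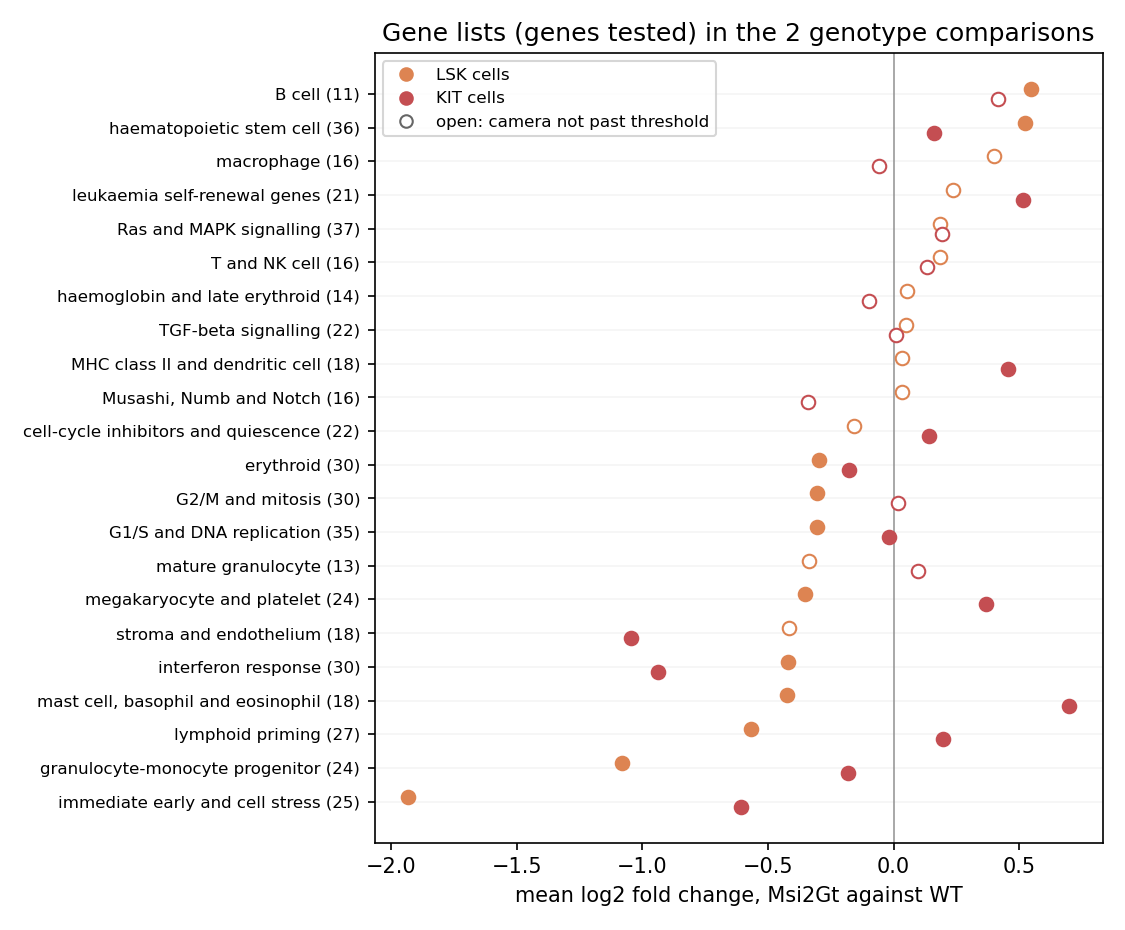
Mean log2 fold change of Msi2Gt against WT (x axis) for each gene list (y axis, with the number of genes tested) in LSK and KIT cells. Filled points passed camera and open points did not; immediate early genes lie at -1.93 in LSK cells, and stroma and endothelium at -1.05 and interferon response at -0.94 in KIT cells, where normexp gave -0.49 and -0.65.

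The same comparison in KIT cells asks how expression differed in the more committed progenitors, also measured in bulk. The interferon response, immediate early and stromal lists fell, while the leukaemia self-renewal, megakaryocyte and mast cell, basophil and eosinophil lists rose. Ifit1 and Oas2, antiviral effectors, fell by 2.25 log2 units (SE 0.14) and 2.01 (SE 0.08). Prg2, the eosinophil granule major basic protein, rose by 2.61 (SE 0.08), and Meis1, a homeobox partner of Hox proteins, by 1.01 (SE 0.09). Of the 22555 genes 747 rose and 434 fell past the threshold, 1181 in all. Of these calls 70 (41 up, 29 down) compare signals below background on every KIT array. A change of at least 2-fold was fitted for 426 (261 up, 165 down), and for 324 with genes at their bound.

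The largest increases were Ccnb1ip1, at least 72.8-fold higher (adjusted p = 1.33e-05), and the dynein heavy chain gene Dnahc2, within 20 Mb of Msi2, at least 51.7-fold (adjusted p = 3.39e-05). The eosinophil ribonuclease gene Ear7, on chromosome 14, was at least 5.64-fold higher (adjusted p = 0.000349). Fcer1a, a chain of the high-affinity IgE receptor, rose by 4.10 (SE 0.39, adjusted p = 0.000982) and Rpl39l, a ribosomal protein paralogue, by 4.07 (SE 0.12, adjusted p = 7.08e-06). Among the largest decreases, beside Msi2, Col1a1 was at least 26.6-fold lower (adjusted p = 9.64e-06) and Btc, a ligand of the EGF receptor, at least 7.04-fold lower (adjusted p = 0.00347). Col1a1 also lies within 20 Mb of Msi2. Fos fell by 5.34 (SE 0.19, adjusted p = 1.33e-05) and Slfn8 by 3.98 (SE 0.50, adjusted p = 0.00353), although the other Slfn8 probe rose by 0.55 (SE 0.09, adjusted p = 0.0213).

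The interferon response list had the lowest p, with 19 of 30 members lower and 0 higher (23 and 0 over the list alone), a mean of -0.94 and an adjusted p of 2.79e-32. Ifi44 fell by 2.39 (SE 0.11). Xaf1 fell by 1.79 (SE 0.14) on its brightest probe, but its other probe rose by 4.61 in KIT and 5.76 in LSK cells (SE 0.14 and 0.11). The immediate early list had 5 of 25 lower and 1 higher (11 and 2 over the list alone), with a mean of -0.61 (-0.36 with normexp) and an adjusted p of 2.30e-06. In it Jun fell by 3.74 (SE 0.14), Fosb by 1.48 (SE 0.22) and Dusp1 by 1.25 (SE 0.14). Stroma and endothelium had 8 of 18 lower, 1 of them below background on every KIT array, and 0 higher (9 and 0 over the list alone), with a mean of -1.05 (-0.49 with normexp, -0.57 in the authors' values) and an adjusted p of 1.22e-09. Its median was -0.50, or -0.15 with members below background at their bound, and -0.05 with normexp. The matrix protein gene Sparc fell by 3.55 (SE 0.13), Col1a2 by 2.31 (SE 0.11) and the chemokine gene Cxcl12 by 1.86 (SE 0.13). The means of these 3 lists were -0.95, -0.58 and -1.08 with slide as a block, and -0.93, -0.57 and -1.16 within slide 2.

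The leukaemia self-renewal list had 10 of 21 members higher and 0 lower, also over the list alone, with a median of 0.42 (0.19 at the bounds, 0.14 with normexp, 0.03 in the authors' values) and an adjusted p of 1.35e-05. Its mean was 0.52, but 0.27 with normexp and 0.23 in the authors' values. Hoxa10 was at least 4.02-fold higher, Hoxa1 rose by 2.51 (SE 0.31) and Hoxa3 by 1.01 (SE 0.10). Megakaryocyte and platelet genes had 9 of 24 higher and 0 lower (11 and 1 over the list alone), with a mean of 0.37 and an adjusted p of 2.30e-06. The platelet chemokine gene Pf4 rose by 1.14 (SE 0.12) and Plek, pleckstrin, by 0.89 (SE 0.07). The mast cell, basophil and eosinophil list had 7 of 18 higher and 1 lower (7 and 2 over the list alone), with a mean of 0.70 (0.41 in the authors' values) but a median of 0.14 (0.12 at the bounds) and an adjusted p of 0.000982. Ms4a2, another chain of the IgE receptor, rose by 2.01 (SE 0.13), and Epx, eosinophil peroxidase, by 1.84 (SE 0.17). The haematopoietic stem cell list had 9 of 36 higher, 1 of them below background on every KIT array, and 4 lower (12 and 4 over the list alone), with a mean of 0.16 (0.09 with quantile normalization), a median of 0.26 at the bounds too and an adjusted p of 0.00133. Vldlr, a lipoprotein receptor, rose by 1.63 (SE 0.09), while Ly6a fell by 1.12 (SE 0.09, adjusted p = 0.000512) and the endothelial receptor gene Tie1 by 1.26 (SE 0.16). These 4 lists, blocked by slide, had means of 0.59, 0.35, 0.63 and 0.18, and within slide 2 0.51, 0.36, 0.57 and 0.21.

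The erythroid list had 2 of 30 lower and 0 higher (3 and 0 over the list alone), with a mean of -0.18 and an adjusted p of 5.85e-06; Ctse fell by 0.58 (SE 0.09) and Uros, a haem synthesis gene, by 0.46 (SE 0.08). In the G1/S list Ccnd1 rose by 1.86 (SE 0.09) and the other 34 members did not pass, also over the list alone; the mean was -0.02 and the adjusted p 0.0136. Each of the next 4 calls was lost with an estimated correlation. Granulocyte-monocyte genes had 6 of 24 lower and 2 higher (7 and 2 over the list alone; adjusted p = 0.000821, but adjusted p = 0.191 with an estimated correlation), with F13a1 down by 0.94 (SE 0.14) and the lysozyme gene Lyz2 by 0.92 (SE 0.12). Lymphoid priming had 6 of 27 higher and 2 lower (7 and 3 over the list alone; 0.0230, but adjusted p = 0.146 with an estimated correlation), with Dntt up by 0.75 (SE 0.12) and the cytokine receptor gene Flt3 by 0.99 (SE 0.11). MHC class II and dendritic cell genes had 3 of 18 higher and 0 lower (6 and 0 over the list alone; 0.00793, but adjusted p = 0.146 with an estimated correlation), with H2-Eb1 up by 2.45 (SE 0.15). Cell-cycle inhibitors had 3 of 22 higher and 1 lower (5 and 1 over the list alone; 0.0136, but adjusted p = 0.223 with an estimated correlation). The lymphoid and MHC class II medians were 0.19 and 0.28, or 0.16 and 0.195 at the bounds. The MHC class II mean of 0.46 was 0.25 with normexp and 0.21 in the authors' values, where the lymphoid mean of 0.20 was 0.09 and the inhibitor mean of 0.14 was 0.07.

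No call was made for G2/M and mitosis (limma, 0 of 30 members past the threshold and 0 at an unadjusted p under 0.05; adjusted p = 0.405), in which Top2a changed by -0.22 (SE 0.10, adjusted p = 0.315). The same held for TGF-beta signalling (0 of 22 by limma, 4 at an unadjusted p under 0.05, 3 higher and 1 lower; 0.690), Musashi, Numb and Notch, where only Msi2 passed (1 of 16; 0.423), and Ras and MAPK signalling (1 of 37; 0.300). Nor did B cell genes pass (2 of 11 higher; 0.211), T and NK cell genes (2 of 16 higher; 0.101), 1 of the 2 in each list being below background on every KIT array, haemoglobin and late erythroid genes (1 of 14 higher, 1 lower; 0.0968), macrophage genes (1 of 16 higher, 1 lower; 0.690) or mature granulocyte genes (1 of 13 higher, 1 lower; 0.916). Kit changed by 0.01 (SE 0.10, adjusted p = 0.988).

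In KIT cells 13 of the 22 lists passed and 9 hold with an estimated correlation. All 13 kept the sign of their mean with slide as a block (largest difference 0.09) and within slide 2 (0.13), as did all called genes (100%). For called genes the sign within slide 2 was close to fixed in advance, as its arrays are in the fit. Mean, median and test differed in sign for G2/M (0.02, -0.01, lower), macrophage (-0.06, 0.03, lower), mature granulocyte (0.10, 0.17, lower), Musashi, Numb and Notch (-0.34, 0.05, lower) and TGF-beta signalling (0.01, -0.08, lower). At the bounds the medians of the last 4 were 0, 0, 0.0099 and -0.06. The mean changed sign with median scaling and the authors' table for G2/M, with normexp for macrophage, with the authors' table for mature granulocytes, and with quantile normalization, median scaling and the authors' table for TGF-beta signalling. Calls here depended on pooling the spread over the 4 groups: 34 genes were called from the KIT arrays alone, and 13 with slide as a fixed block. Of the genes named in this part, that block kept only the calls of Msi2, Ccnb1ip1, Dnahc2, Rpl39l, Col1a1, Fos, Jun and Prg2. Another background correction (normexp) left 377, without Btc, Fosb, Dusp1, Hoxa1, Hoxa3, Tie1, Ctse, Uros, Lyz2 and Dntt, and the authors' deposited values 588, without Tie1, Ctse and Dntt, and leaving out KIT Msi2Gt replicate 1 or 2 left 776 or 753. Without KIT WT replicate 1 the calls of cell-cycle inhibitors (adjusted p = 0.125) and MHC class II (0.117) were lost, and haemoglobin (0.0436) and T and NK cell genes (0.0263) passed. Without KIT WT replicate 2 or KIT Msi2Gt replicate 1 the calls of G1/S (0.0789 and 0.0774, and 0.0990 by fry) and lymphoid priming (0.0617 and 0.0624) were lost. T and NK cell genes also passed without KIT Msi2Gt replicate 2 (0.0291). In the authors' values the calls of G1/S (0.0614), lymphoid priming (0.0787) and cell-cycle inhibitors (0.139) were lost.

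The interaction term asked whether the genotype effect differed between the gates. It did for 1761 genes, 923 with a higher and 838 with a lower change in LSK cells, and 934 of these differed by at least 2-fold (565 and 369). The count was 1171 without LSK WT replicate 1, 957 with normexp, 1149 with no filter and 290 with slide as a fixed block. Lower changes outnumbered higher ones with the filter over all arrays (580 higher, 726 lower), an intensity trend in the prior (853, 1025) and slide as a random block (1141, 1183). Sparc rose by 2.04 in LSK cells and fell in KIT cells, a difference of 5.59 (SE 0.17, adjusted p = 2.78e-05). The next highest differences were 5.42 for Btc (SE 0.75, adjusted p = 0.00443), 5.15 for Cfd (SE 0.29, adjusted p = 0.000108), 4.44 for Ighg (SE 0.66, adjusted p = 0.00609) and 4.38 for Rgs4, a regulator of G protein signalling (SE 0.29, adjusted p = 0.000185). The lowest were -7.19 for Col10a1 (SE 1.63, adjusted p = 0.0381), -5.14 for Prg4 (SE 0.38, adjusted p = 0.000262) and -4.05 for Dnahc2 (SE 0.40, adjusted p = 0.000897). Cecr6 followed with -3.91 (SE 0.41, adjusted p = 0.00128) and Upb1, an enzyme of pyrimidine breakdown, with -3.82 (SE 0.46, adjusted p = 0.00238). Differences that rest on a group below background are fitted values, not bounds.

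Among the lists, the change in LSK cells was below that in KIT cells for immediate early genes (16 of 25 members lower, 0 higher, mean difference -1.33, camera adjusted p = 8.98e-18) and granulocyte-monocyte genes (13 of 24, 0, -0.90, 3.62e-13). Mast cell, basophil and eosinophil genes (11 of 18 lower, 1 higher, -1.12, 7.90e-10) and lymphoid priming genes (12 of 27, 0, -0.77, 1.36e-09) followed, the former and megakaryocyte genes (12 of 24 lower, 2 higher, -0.72, 2.02e-08) having fallen in LSK and risen in KIT cells. Differences were smaller for G2/M (2 of 30 lower, 0 higher, -0.32, 5.60e-06), G1/S (5 of 35, 0, -0.29, 2.68e-05) and leukaemia self-renewal genes (8 of 21, 0, -0.28, 7.99e-05). The change in LSK cells lay above that in KIT cells for interferon response genes (12 of 30 higher, 0 lower, 0.52, 2.32e-10), stem cell genes (11 of 36 higher, 3 lower, 0.37, 0.00320) and stroma and endothelium (7 of 18 higher, 3 lower, 0.63, 0.00718). The call of stroma and endothelium was lost, with adjusted p = 0.129 with an estimated correlation; the other 10 hold. That call was also lost with normexp (adjusted p = 0.329, median -0.22) and in the authors' values (0.370, median -0.15), against a median of 0.315, and the leukaemia call in the authors' values (0.0521). Adjusted over the list alone, the lower and higher members numbered 17 and 0 for immediate early, 15 and 1 for granulocyte-monocyte, 13 and 1 for mast cell, 16 and 0 for lymphoid and 13 and 2 for megakaryocyte genes. They numbered 4 and 0 for G2/M, 12 and 0 for G1/S and 10 and 1 for leukaemia self-renewal genes, and 3 and 20 for interferon, 5 and 14 for stem cell and 4 and 8 for stromal genes. With normexp the means of interferon, stromal and leukaemia genes were 0.27, 0.31 and -0.17, and in the authors' values 0.29, 0.39 and -0.15, with -0.17 for G1/S. All 11 kept their sign with slide as a block and within slide 2, with largest differences of 0.05 and 0.19. Cell-cycle inhibitors passed without LSK WT replicate 2 (adjusted p = 0.0147), macrophage genes without KIT WT replicate 2 (0.0278) and MHC class II without KIT WT replicate 2 (0.0160) or KIT Msi2Gt replicate 2 (0.0496).

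Of the genes called in both gates, 520 rose in both, against 93.4 expected if the calls were independent, and 223 fell in both, against 53.8. The calls are not independent by design, as both comparisons use 1 estimate of each gene's spread and the same genotype pools. A difference between pools would thus be seen in both gates. Another 138 changed in opposite directions. Across all genes, which are not independent, the changes in the 2 gates correlated with r = 0.293, and with r = 0.597 among genes called in KIT cells.

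**Figure D4:**
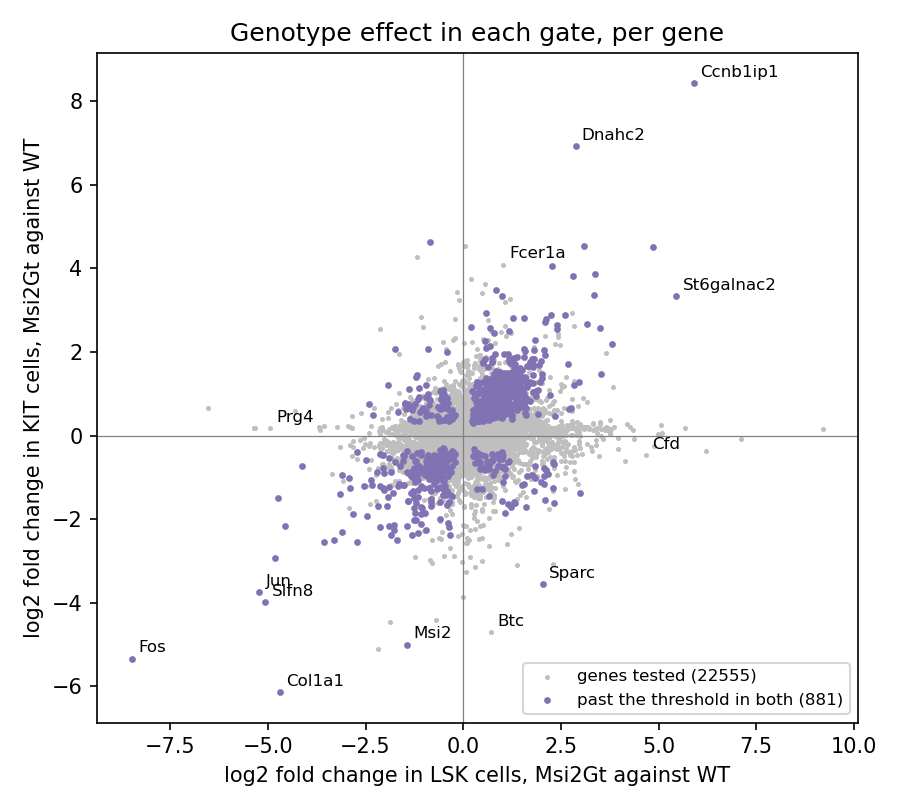
Each point is a gene at its log2 fold change of Msi2Gt against WT in LSK (x axis) and KIT cells (y axis). Genes past the threshold in both gates are purple; Fos, Jun, Slfn8 and Col1a1 lie low in both, Ccnb1ip1 and St6galnac2 high in both, and Sparc on opposite sides.

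LSK was compared with KIT in WT mice to show how the gates differ without the trap. The stem cell, lymphoid, interferon, and stroma and endothelium lists were higher in LSK cells, and the erythroid, haemoglobin, G1/S and G2/M lists higher in KIT cells. Ly6a, which separates the gates, was 3.33 log2 units higher in LSK cells (SE 0.08, adjusted p = 3.91e-08), and Kit 0.52 higher (SE 0.09, adjusted p = 0.00161). Robo4, a receptor of stem and endothelial cells, was 7.38 higher (SE 0.12), and Add2, beta-adducin of the red cell membrane skeleton, was at -4.34 (SE 0.12, adjusted p = 5.15e-08). Higher in LSK cells were 7078 genes and lower 6575, 13653 in all. More were lower than higher under the 4 other scalings (5454 higher and 6007 lower with normexp, 6459 and 7287 with quantile normalization, 6266 and 7717 with median scaling, 6226 and 7040 in the authors' values), with the filter over all arrays (5404 and 6414) and without LSK WT replicate 2 (6704 and 6999). There were 6424 calls fitted at 2-fold or more (4422 higher and 2002 lower) and 6024 with genes at their bound. The other large increases were Igj, the immunoglobulin joining chain, at least 299-fold (adjusted p = 8.26e-08), Mmrn2, an endothelial matrix protein, at least 167-fold (1.02e-08), and the collagen gene Col4a1, at least 61.3-fold (7.96e-09). Sgsm1 was at least 55.8-fold higher (1.78e-08) and Crispld1 at least 48.8-fold (1.24e-07). Beside Add2, the large decreases were Acmsd, of tryptophan breakdown (-5.11, SE 0.97, adjusted p = 0.00209), the oxidase gene Cyp1a1 (-4.46, SE 0.26, 2.63e-06), the transporter gene Osta (-4.39, SE 0.29, 5.03e-06) and Cecr2, at least 12.7-fold lower (3.01e-05).

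In the WT gates 19 of the 22 lists passed camera. The stem cell list had 31 of 36 members higher in LSK cells and 3 lower, the same over the list alone, with a median of 3.25 (2.97 at the bounds) and an adjusted p of 1.02e-10. Interferon response genes were higher at 24 of 30 (0 lower, median 1.23, 4.77e-08), immediate early genes at 21 of 25 (3 lower, median 2.75, 2.56 at the bounds, 2.29e-06) and lymphoid priming genes at 21 of 27 (4 lower, median 2.42, 2.23 at the bounds, 3.08e-06). Stroma and endothelium had 13 of 18 higher and 1 lower (median 2.03, 1.84 at the bounds, 0.000162). Dntt was 7.54 higher (SE 0.11) and Ifit3 4.36 (SE 0.15). Erythroid genes were lower at 28 of 30 (1 higher, median -3.23, 1.43e-14), haemoglobin genes at 10 of 14 (0 higher, median -2.18, 5.17e-05), G1/S genes at 28 of 35 (2 higher, median -0.81, 1.72e-06) and G2/M genes at 21 of 30 (3 higher, median -0.65, 9.40e-05). Some of these medians were smaller by over 1.5 times with normexp and in the authors' values: 2.05 and 1.82 for stem cell, 1.80 and 1.515 for immediate early and 1.165 and 1.05 for stromal genes. With quantile normalization and in the authors' values they were -0.38 and -0.49 for G1/S and -0.40 and -0.37 for G2/M genes, and with normexp -1.385 for haemoglobin genes. Adjusted over the list alone the counts of these lists were the same, except for 22 lower G2/M genes and 2 lower stromal genes. The haemoglobin chaperone gene Ahsp was -4.13 (SE 0.10) and the cyclin gene Ccne1 -3.22 (SE 0.07). Granulocyte-monocyte genes split, 11 of 24 higher and 11 lower (mean -0.35, median 0.10, 0.331), with Ms4a3 at -2.77 (SE 0.09) and Lyz1 at 2.69 (SE 0.15). Mature granulocyte genes (mean 0.05, median -0.26, 0.680), whose mean changed sign under all 4 scalings, and Ras and MAPK signalling (0.0874) did not pass either.

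With slide as a block and within slides 2 and 3, all 19 lists kept their sign, with largest differences of 0.11, 0.22 and 0.25. Of the called genes 100% kept theirs with the block, 99.98% within slide 2 and 99.99% within slide 3. Calls of 5 lists were lost with an estimated correlation: leukaemia self-renewal (adjusted p = 0.0655), mast cell (adjusted p = 0.0536), B cell (adjusted p = 0.0938), T and NK cell (adjusted p = 0.153) and Musashi, Numb and Notch (adjusted p = 0.126). Other scalings moved the median of all genes, LSK against KIT in WT, by -0.08 (normexp), -0.10 (quantile), -0.15 (median scaling) and -0.05 (authors' table), and in Msi2Gt by -0.11, -0.17, -0.13 and -0.10. Without KIT WT replicate 2 the T and NK cell call was lost (adjusted p = 0.0846), and Ras and MAPK signalling passed without LSK WT replicate 2 (0.0374). Quantile normalization ended the calls of T and NK cells (0.0828) and Musashi, Numb and Notch (0.0539), and Ras and MAPK signalling passed (0.0145). Means were smaller by over 1.5 times for 8 of the 19 lists with normexp, 10 in the authors' values and 2 with quantile normalization, and 0 changed sign. The T and NK cell call was lost with normexp (0.108) and in the authors' values (0.0882), the B cell call with normexp (0.0587) and the Musashi call in the authors' values (0.0970), while Ras and MAPK signalling passed with both (0.0465 and 0.00858).

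The gates were also compared within Msi2Gt mice, to show how they differ with the trap. The stroma and endothelium, stem cell and interferon lists were again higher in LSK cells. Granulocyte-monocyte genes passed as lower by camera, a call lost with adjusted p = 0.148 with an estimated correlation. Mmrn2 was at least 726-fold higher (adjusted p = 2.70e-09), Igj at least 331-fold (5.65e-08), Gpr182 at least 223-fold (5.05e-08) and the tetraspanin gene Tspan7 at least 208-fold (1.73e-08). The fatty acid carrier gene Fabp4 was 9.65 log2 units higher (SE 0.09, 2.70e-09). Lower were Olr1, a receptor of oxidised lipoprotein, at least 7.79-fold (adjusted p = 4.66e-06), Cyp1a1, at least 16.3-fold (1.16e-06), Tctex1d1, at least 8.99-fold (4.50e-06), Osta, at least 22.5-fold (2.89e-06), and Tspan8 (-4.63, SE 0.12, 3.34e-08). Ly6a was 4.25 higher (SE 0.08, 1.33e-08), Kit 0.79 (SE 0.09, 0.000124) and Msi2 5.08 (SE 0.08, 8.97e-09). In all, 7224 genes were higher and 6989 lower (14213), 7333 of them fitted at 2-fold or more (4662 and 2671) and 6897 with genes at their bound. More were lower than higher with normexp (5546 higher and 6637 lower), quantile normalization (6524 and 7722), median scaling (6544 and 7837), the authors' values (6297 and 7491) and the filter over all arrays (5377 and 6832).

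Of the 22 lists 18 passed in Msi2Gt mice. The stem cell list had 32 of 36 higher and 3 lower (median 3.28, 3.24 at the bounds, adjusted p = 1.36e-11), interferon response genes 29 of 30 and 0 (median 1.74, 8.39e-10) and stroma and endothelium 14 of 18 and 2 (median 2.58, 1.38 at the bounds, but 0.69 with normexp and 0.66 in the authors' values, 9.10e-05). Erythroid genes had 28 of 30 lower and 1 higher (median -3.33, 1.81e-13), G1/S genes 30 of 35 and 2 (median -0.97, 3.39e-08) and G2/M genes 24 of 30 and 2 (median -0.92, 2.82e-06). The medians of the latter 2 were -0.54 and -0.59 with quantile normalization and -0.57 and -0.58 in the authors' values. Granulocyte-monocyte genes had 16 of 24 lower and 5 higher (median -0.89, -0.496 with quantile normalization and -0.49 in the authors' values, 0.000589, but adjusted p = 0.148 with an estimated correlation), with Ms4a3 at -4.54 (SE 0.09) and F13a1 at -4.30 (SE 0.12). Immediate early genes had 15 of 25 higher and 5 lower (median 1.17, 0.48 at the bounds, but 0.75 with quantile normalization, 0.15 with normexp and 0.16 in the authors' values, 0.0177), a call lost with adjusted p = 0.128 with an estimated correlation. Their mean was 0.99, but 0.53 with normexp and 0.50 in the authors' values. The counts of these 8 lists adjusted over the list alone were the same, but for 31 lower G1/S genes. Beside granulocyte-monocyte and immediate early genes, 5 lists lost their call with an estimated correlation: leukaemia self-renewal (adjusted p = 0.120), Musashi, Numb and Notch (adjusted p = 0.148), T and NK cell (adjusted p = 0.176), B cell and cell-cycle inhibitors (adjusted p = 0.0945 for both). Quantile normalization ended the calls of immediate early genes, the Musashi list (0.0551 for both) and T and NK cells (0.132), and Ras and MAPK signalling passed (0.0120). The Musashi call was lost without LSK Msi2Gt replicate 2 (0.0505) or 3 (0.0571) or KIT Msi2Gt replicate 1 (0.0529), and the T and NK cell call without LSK Msi2Gt replicate 1 (0.0616) or KIT Msi2Gt replicate 2 (0.0577) or with the replicate block (0.0588). Means were smaller by over 1.5 times for 7 of the 18 lists with normexp, 8 in the authors' values and 2 with quantile normalization, and 0 changed sign. The T and NK cell call was lost with normexp (0.173) and in the authors' values (0.178), and the Musashi call in the latter (0.0734), while megakaryocyte genes passed with normexp (0.0400) and Ras and MAPK signalling in the authors' values (0.01). Megakaryocyte (0.117), Ras and MAPK (0.117), mature granulocyte (0.359) and mast cell lists (8 of 18 higher and 8 lower, 0.683) did not pass; the mean of the last was 0.14, its test pointed lower, and the mean changed sign under 3 scalings. With slide as a block and within slides 2 and 5 the 18 lists kept their sign, with largest differences of 0.03, 0.21 and 0.21, as did all called genes (100%).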

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

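The tests of the explanations in this part, the split of the LSK arrays included, were written down after the results were seen. The interaction term itself was planned. Each value here is the genotype change in LSK cells minus that in KIT cells, in log2 units, and passed limma's test of that difference, or camera's for a list. With slide as a fixed block 290 genes passed limma's test, all of them with a difference of at least 2-fold.

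Msi2 fell less in LSK than in KIT cells, a difference of 3.57. The tables argue against wild-type RNA in the mutant LSK samples, since a share that keeps Msi2 at 37.1% would keep every gene near that level: 20 genes above the 75th percentile in WT fell by over 2 log2 units. They also argue against the scaling and background correction, as the lowest difference over 4 alternatives was 2.82. The other 2 Msi2 probes, 394.3 kb away, moved the opposite way. A candidate explanation that stays open, untested because the insertion site is not given, is that more transcript passes the trap, or starts beyond it, in LSK cells.

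The immediate early list passed as lower in both gates, more so in LSK cells, with a mean difference of -1.33 for the list, -3.15 for Fos, -1.48 for Jun, -3.26 for Fosb and -1.65 for Dusp1, while Nr4a1 (-2.80) fell in LSK cells and rose by 0.50 in KIT cells. The tables argue against slide or scan, since the list's mean in LSK cells was -1.93 with slide as a block. They also argue against fewer cells of every other type alike in the mutant LSK samples. Of 88 tested members of 6 lists of such cells, 22 rose and 18 fell past the threshold. Those lists were B cell, T and NK cell, macrophage, mature granulocyte, haemoglobin and late erythroid, and stroma and endothelium, without MHC class II and dendritic cell. Different handling of the genotype pools cannot be told apart from genotype, as each genotype is 1 pool. The immediate early list responds to cell handling, and 5 of its members fell in both gates, as a handling difference of a pool would need. Fewer stromal cells alone in the mutant samples stay open, untested, as Col1a1 and Col1a2 fell in both gates too, by 4.69 and 3.11 in LSK cells. So did the bone and matrix genes Bglap2, Lum and Ibsp, chosen after their values were seen. Their changes in LSK and KIT cells were -4.80 and -2.93, -2.71 and -2.54, and -1.89 and -2.17. Not every matrix gene fell, as Sparc rose by 2.04 in LSK cells and the collagen gene Col4a1 rose in both gates (1.42 and 1.45). Bulk arrays do not show whether these genes come from the same cells as Col1a1 and Bglap2, so their rise does not decide the question. Both gates were also sorted as lineage-negative and c-Kit-positive. An effect of Msi2 on the immediate early genes stays open too, as untested.

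Genes that changed at least 2-fold in the same direction in both gates, 198 by fitted values, lay near Msi2 more often than elsewhere. Without Msi2, 24 of 908 genes within 20 Mb were among them, against 173 of 21453 others (odds ratio 3.34, 95% confidence interval 2.07 to 5.17, two-sided Fisher's exact p = 1.65e-06). The tables argue against an effect of the insertion on the genes beside it alone, since the odds ratio was still 2.95 (1.75 to 4.73, exact p = 5.66e-05) from 10 to 30 Mb away. A strain segment around the targeted gene may account for it and stays open: the labels name C57/Bl6 but not the strain the trap was made in. Genes on a chromosome are not independent, no sequence was measured, and a biological explanation was not tested.

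In LSK cells 5615 genes were called. The 10 splits of the 6 LSK arrays into 3 and 3 are too few for a share under 0.05. The real split gave 5615 genes, as many as 1 of the 10 splits, and the highest other was 196. Every other split mixes the genotypes, which puts their difference into the spread, so low counts there follow from the grouping. The arrays are technical replicates, so the splits cannot test chance between animals.

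Among lists, the change in LSK cells was lower for mast cell, basophil and eosinophil (-1.12), granulocyte-monocyte (-0.90), lymphoid priming (-0.77), megakaryocyte (-0.72), G2/M (-0.32), G1/S (-0.29) and leukaemia self-renewal genes (-0.28). It was higher for interferon response (0.52) and stem cell genes (0.37), and for stroma and endothelium (0.63), whose call was lost with adjusted p = 0.129 with an estimated correlation and with adjusted p = 0.329 with normexp, where its median was negative (-0.22). The leukaemia call was lost in the authors' values (adjusted p = 0.0521).

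Single genes of the progenitor lists differed between the gates. In the granulocyte-monocyte list the differences were -2.32 for Ctsg, -2.15 for F13a1, -1.77 for Ms4a3 and -1.63 for Hp. In the lymphoid list they were -3.16 for Dntt, -1.93 for Rag1, -1.40 for Rag2, -1.77 for Il7r and -1.90 for Flt3. For erythroid and megakaryocyte genes they were -1.92 for Ctse, -0.67 for Gata1, -1.81 for Itga2b, -1.51 for Itgb3, -2.27 for Pf4 and -1.78 for Plek. For mast cell and eosinophil genes they were -3.08 for Fcer1a, -2.43 for Ms4a2, -2.40 for Prg2, -2.08 for Cpa3, -1.41 for Hdc and -1.28 for Epx.

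Stem cell and related genes differed by 2.84 for Sult1a1, 1.08 for Abcb1a, 0.94 for Mllt3, 0.91 for Ly6a, 1.496 for Tie1, 1.65 for Robo4 and -1.74 for Vldlr. Homeobox genes of the leukaemia list differed by -1.89 for Hoxa10 and -0.62 for Meis1. Cell-cycle genes differed by -0.54 for Mcm2, -0.49 for Mcm3, -0.57 for Ccnd1 and -0.64 for Cks2. Interferon response genes differed by 1.29 for Ifit1, 1.40 for Oas2, 2.05 for Ifi44 and 1.45 for Xaf1, whose other probe moved the opposite way in both gates.

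Macrophage, stromal and endothelial genes differed by 2.94 for Mrc1, 1.59 for Vcam1, 1.45 for Col1a1, -0.80 for Col1a2, 2.54 for Flt4, 5.59 for Sparc, 0.87 for Cxcl12, 3.93 for Mmrn2 and 2.76 for Fabp4. Signalling genes differed by 1.95 for Rasgrp1, 2.24 for Id3, 1.94 for Dll1 and -1.23 for Dtx4, and the MHC class II gene H2-Eb1 by -1.65. The largest changes of single comparisons differed by -2.53 for Ccnb1ip1, 2.12 for St6galnac2, 5.15 for Cfd, 4.44 for Ighg, 2.68 for Bmpr1a, -7.19 for Col10a1, -5.14 for Prg4, -4.05 for Dnahc2, -1.79 for Rpl39l and 5.42 for Btc. The remaining differences were 4.38 for Rgs4, -3.91 for Cecr6, -3.82 for Upb1, -1.12 for Sgsm1, 3.91 for Gpr182, 3.17 for Tspan7 and -2.15 for Tctex1d1. Differences in this part that rest on a group below background are fitted values, not bounds, and their size is uncertain. Among them, Mmrn2 was below background on every KIT array of both genotypes, and Gpr182 and Tspan7 on every KIT Msi2Gt array.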

How the results depend on the processing

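The alternatives here were planned, except camera with normexp, median scaling and the authors' table, which was chosen after seeing the data, and the cause of a difference was not tested unless one is named. Of the lists that passed camera, 0 changed the direction of the test with these, quantile normalization, fry, the replicate block, an estimated correlation or a left-out array, and 0 the sign of the mean under the 4 scalings, but the interaction median of stroma and endothelium turned negative with normexp and in the authors' table. The report gives the calls lost and the other lists whose mean changed sign. Of 96 and 63 calls of leading genes in LSK and KIT cells, normexp kept 84 and 38, the authors' values 89 and 48, the groups of the comparison alone 90 and 16, and slide as a fixed block 48 and 8. Within slide 2 all kept their direction, which was close to fixed in advance, as its arrays are in the fit. With normexp the counts at 2-fold were 662 in LSK, 101 in KIT, 4124 between gates in WT and 516 for the interaction, and at any size 377 in KIT and 957 for the interaction. With the authors' table they were 643, 102, 3575 and 528 at 2-fold, 4238 between gates in Msi2Gt, and 588 in KIT at any size. With the filter over all 10 arrays, which tests 18518 genes, they were 630 in LSK, 231 in KIT and 450 for the interaction at 2-fold, and with no filter the interaction count was 1149. The KIT arrays alone gave 34 calls, all at 2-fold, from fewer samples. With slide as a fixed block, which leaves 2 residual degrees of freedom, the counts were 715 (674 at 2-fold) in LSK, 13 (13) in KIT and 290 (290) for the interaction; as a random block they were 6138, 1475 and 2324.

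Leaving out 1 array gave 3994 to 5630 calls in LSK, 753 to 1095 in KIT and 1171 to 1437 for the interaction, of 5615, 1181 and 1761. Leaving out KIT Msi2Gt replicate 1 or 2 moved the KIT count by over 1.5 times (776 and 753), as leaving out LSK WT replicate 1 did for the interaction (1171). A lone array was then assumed to vary like the other groups. Without LSK WT replicate 2, which stood apart, 5558 were called in LSK cells, of which 4650 were shared with the main fit. Then 3234 rose and 2324 fell, against 2820 and 2795, and 1712 changed by at least 2-fold, against 1443. The fry test passed 17 lists in LSK cells and 17 for the interaction, against 11 and 11. In KIT cells it ended the G1/S call (adjusted p = 0.0990) and gained Musashi, Numb and Notch (0.000173), and between gates it gained 3 lists in WT and 4 in Msi2Gt. With the mean over a gene's probes Msi2 changed by 0.76 in LSK cells and Xaf1 by 1.41 in KIT cells, since their probes move apart. The change of Kit in KIT cells, not called, was -0.0085 with normexp, -0.0081 with median scaling, -0.02 with the authors' table and -0.0193 to 0.0433 over left-out arrays. Signal over background limits folds of dim genes to bounds.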

Other observations

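The gene families in this part, the immunoglobulin segments, and the tests of position were chosen after the data were seen.

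Immunoglobulin transcripts, which mark B and plasma cells, moved both ways in LSK cells. Of 85 variable segments tested 34 rose and 27 fell, from at least 13.7-fold higher (IGKV8-21) to at least 13.5-fold lower (IGKV3-2) among those below background in a genotype, and of 8 constant segments 4 rose and 2 fell. The gamma constant segments IGHG3 and IGHG2C were far higher in Msi2Gt, IGHG3 at least 242-fold (adjusted p = 5.01e-05) and IGHG2C by 6.23 (adjusted p = 3.24e-05), while the mu segment IGHM fell by 0.26 (adjusted p = 0.0304). Each genotype was 1 pool, so these p-values measure the spread between arrays and cannot separate genotype from the cells of that pool. In KIT cells 1 constant segment, IGLC3, rose from below background on both WT arrays (adjusted p = 0.00772), and 0 segments fell. The 2 variable segments called there were below background on every KIT array. In WT mice 68 of the 85 variable segments were higher in LSK than in KIT cells and 0 lower.

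Families by symbol stem were tested with camera, 173 with at least 10 tested members. In LSK cells 18 passed, 16 lower and 2 higher, and 0 hold with an estimated correlation. Histone genes (Hist) fell at 26 of 46 (0 rose, median -0.49, adjusted p = 1.74e-10, and adjusted p = 0.850 with an estimated correlation), mitochondrial ribosomal genes (Mrpl) at 11 of 44 (0 rose, median -0.18, adjusted p = 0.000442) and RNA polymerase genes (Polr) at 11 of 27 (0 rose, median -0.20, adjusted p = 0.00146). In the protocadherin beta cluster 6 of 14 rose and 0 fell (median 0.82, adjusted p = 0.00538). The other higher family was the olfactory receptors (Olfr), where 10 of 263 rose and 1 fell (median 0.35, adjusted p = 0.0162). The Olfr median was 0.17 with normexp, 0.10 with quantile normalization and 0.03 in the authors' values. These medians kept their sign under all 4 scalings in LSK cells, but in the authors' values they shrank to -0.10 for Mrpl (-0.11 with quantile normalization), -0.13 for Polr and 0.20 for the protocadherins (0.38 with normexp). In KIT cells 1 family passed: 6 of 11 Hoxa genes rose and 0 fell (median 0.77, 0.37 with normexp and 0.34 in the authors' values, adjusted p = 1.07e-05, and adjusted p = 0.744 with an estimated correlation).

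The 198 genes that changed at least 2-fold the same way in both gates, 135 up and 63 down, were not spread evenly. Chromosome 11 held 37 of them, Msi2 included, and chromosome 14 held 26. Of 258 windows of 10 Mb with at least 20 genes, the first 10 Mb of chromosome 14 held 13 of its 52 genes (adjusted exact p = 1.57e-13), and 80 to 90 Mb of chromosome 11 held 7 of 150 without Msi2 (adjusted exact p = 0.0486). All 13 on chromosome 14 rose, by 1.02 to 2.10 log2 units over the gates, and 10 carry placeholder names (Gm or LOC) of predicted genes. The exact test counts such neighbours as independent, and copies of 1 repeated gene, which a probe can share, were not ruled out. A second strain segment, on chromosome 14, is a hypothesis these arrays cannot test, as they hold no sequence.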
